A study of Mus musculus with 6 samples.

How the data were processed

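RNA of sorted mouse bone marrow cells was measured by bulk sequencing in 6 libraries, 3 labelled CD44+CD51- and 3 labelled CD51+, numbered 1 to 3 in each group. CD51 is integrin αV, encoded by Itgav, and CD44 is a receptor for hyaluronan. Per the labels, the animals were of the C57BL/6 strain, the marrow was dissociated with enzymes, and the cells were sorted straight into lysis buffer. RNA was purified with a column kit for small inputs (RNeasy Plus Micro), and libraries were made with the Nextera XT kit, in which a transposase cuts and tags double-stranded DNA. Strand is not kept by that kit in its usual use, so reads from overlapping genes on opposite strands would not be told apart. The labels call the cells TNCs and do not spell the term out. In this field it is used for marrow cells that lack markers of mature blood and endothelial cells, among them CD45 and CD31, whose genes were therefore examined with the sorting genes.

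The deposited table gave RPKM, the reads of a gene per kilobase of its length scaled to library size, as the authors computed it, with 1 column per sample. The submitters' processing notes name the genome build GRCm38 and edgeR 3.16.5, used by the authors. The aligner, the read counter, the annotation version and any adjustment of library size within the RPKM were not given in the sources used here. The table had 25955 entries, of which 4303 were at 0 in all 6 samples. Each of 30 entries shared its symbol with another, and 26 symbols had been turned into dates by a spreadsheet program. Shared symbols were kept apart, with the entry of highest mean standing for the symbol, and date-like symbols were tested without being matched to a gene list.

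Depth was not stated and was estimated from the values. At 1 read a gene's RPKM depends only on gene length and library size, so the commonest ratio of low values between 2 samples gives their relative depth. With gene lengths from GENCODE M21, 89.7% of 32133 values of up to 20 reads came to a whole number within 0.05 read, where 10% would do so by chance. The library size that the RPKM had been divided by, estimated in this way, ran from 12197833 to 32517059 reads. The recovered reads summed to between 17407902 and 48097683 per library, more than that divisor, and the reason for the gap is unknown. Recovered reads were therefore used only for an alternative test and as the base of the simulated sets described below. Where a gene was at 0, a floor of 3 reads was taken with the estimated divisor, which covers counting error only.

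Genes were tested where RPKM was at least 1 in at least 3 of the 6 samples, which left 11741. Values were taken as log2(RPKM + 1), and CD51+ was compared with CD44+CD51- by limma 3.58.1 in R 4.3.3 with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The pseudocount of 1 makes log2 changes of genes with low values smaller than the ratio of their means. A fold beyond 2 was tested with limma's treat at a log2 change of 1. Shares of the summed RPKM were compared by an exact permutation test, two-sided, in which 3 samples against 3 cannot give a p under 0.1. The labels do not say that replicates came from separate animals or cultures, so each p measures only the spread between these samples.

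The main comparison, most of the other settings tried, the rule for named genes and 36 gene lists were fixed before the data were examined. The lists held sort and gate antigens, mesenchymal stromal markers, haematopoietic niche factors, osteolineage, adipogenic and chondrogenic genes, extracellular matrix, erythroid genes, haem and iron handling, B lineage, early haematopoietic progenitor and pan-haematopoietic genes. Markers of other cells that the sort could hold covered endothelial, mural and smooth muscle, Schwann and neural, skeletal muscle, neutrophil lineage, monocyte and macrophage, megakaryocyte, T and NK, osteoclast, and mast, basophil and eosinophil genes. The rest were mitosis, DNA replication, immediate early and heat shock genes, complement, chemokines and cytokines, the BMP and TGF-beta pathway, the Wnt pathway, integrins other than Itgav, glycolysis, oxidative phosphorylation, ribosomal proteins, mitochondrial transcripts, housekeeping genes and the interferon response. A few genes stood in more than 1 list. Counts of a list are out of its members that passed the filter on RPKM, such as 12 of 24 chemokines and cytokines, 19 of 31 Wnt and 4 of 10 osteoclast genes. Members low in both groups were thus left out, while those high in 1 group alone could enter. Each list was tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists. Camera asks whether a list ranks above or below the other genes, and fry whether its genes move on balance in 1 direction, without comparing them with other genes.

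Named genes were Cd44, Itgav, Ptprc, Pecam1 and others of the gate; the 10 largest rises and the 10 largest falls among genes past the test with a mean RPKM of at least 20 in the higher group and no overlap between the groups, predicted genes and antigen receptor segments aside; and, from each list, up to 3 called members with the largest change in the direction of most calls and the 1 with the largest change the other way. Where no member of a list passed, up to 2 of highest mean were taken. Results of a few of these genes, and of the list of sort and gate antigens as a whole, are not reported. Positions are on GRCm38, counted from 1, from GENCODE M21.

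Equal numbers in the 2 groups might mark samples handled together, which the labels do not state, so this was checked on the data. After each group's mean was removed from the log2 values, the libraries of equal number correlated across genes at r = 0.62, 0.29 and 0.52 for numbers 1, 2 and 3. All 3 exceeded the limit of 0.1 set for treating the numbers as pairs. They are not 3 separate checks, since deviations from a group mean sum to 0. A deviation shared by the libraries numbered 1 thus also raises r among numbers 2 and 3. Libraries of unequal number in different groups also reached 0.32 (CD44+CD51- replicate 3 with CD51+ replicate 2) and 0.20 (CD44+CD51- replicate 2 with CD51+ replicate 3), so number 2 did not stand apart from them. The labels do not state pairs, so the block was fixed in advance as an alternative and the main test was kept without it. Values with the number as a block are given beside the list counts that it moved by more than 1.5 times or from 0. Genes are not independent replicates, so these r values carry no p.

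Other settings fixed in advance were pseudocounts of 0.1 and 0.5, no filter beyond a value above 0, RPKM of at least 5 in 3 samples, rescaling by a trimmed mean of log ratios (TMM) computed on the RPKM, quantile normalization, the replicate block, limma without the trend or with a robust prior, leaving out each library in turn, and the share of the 10 highest genes without mitochondrial genes. Those chosen after seeing the data were limma's voom on recovered reads, the block with a GC correction by lowess in each library, leaving out both libraries numbered 1, and rescaling to the sum outside ribosomal RNA and neutrophil genes. The test was checked on 20 simulated sets with the relative depths of these libraries, an assumed coefficient of variation of 20% for every gene and 200 changed genes in each. Their expected reads were built from the recovered reads of the CD44+CD51- libraries, whose sums exceed the divisor, so the recovery rests on them. Changed genes were drawn only from those with enough expected reads in every library, so genes of low abundance were not covered. Some genes, such as Sparc, varied more between libraries here, so the recovery holds for that spread only. The test recovered 65.6% of changes of 2-fold and 99.9% of changes of 4-fold, and 8.10% of its calls were false where the nominal share was 5%. That share holds for sets in which far fewer genes changed than were called here. Lists, tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.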

Results

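Bulk RNA profiles were collected from 2 sorted populations of mouse bone marrow TNCs, 3 libraries of CD44+CD51- cells and 3 of CD51+ cells. The series title names stromal and haematopoietic TNCs, and the comparison asks how the transcripts of the 2 sorted populations differ. The library size that the RPKM had been divided by was estimated from the steps between low RPKM values. It was between 19337050 and 25587855 reads in the CD44+CD51- libraries and between 12197833 and 32517059 reads in the CD51+ libraries. Values are mean RPKM ± SD with n = 3 per group unless stated, log2 changes are CD51+ minus CD44+CD51- on the log2(RPKM + 1) scale, and adjusted p-values are from limma.

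The genes of the sorting antigens were examined first, as a check of the labels. Itgav (chromosome 2, 83724397 to 83806916, plus strand), which encodes CD51, rose from 0.677 ± 0.244 in CD44+CD51- cells to 7.01 ± 2.43 in CD51+ cells (log2 change 2.22, adjusted p = 0.000389). Cd44 was at 34.8 ± 2.57 and 31.5 ± 2.98, a difference within the replicate spread (adjusted p = 0.401). Of the genes of the antigens that a triple-negative gate excludes, Ptprc, which encodes CD45, rose from 3.25 ± 1.28 to 6.87 ± 0.643 (log2 change 0.93, adjusted p = 0.0122). Pecam1, which encodes CD31, was at 2.16 ± 1.09 and 1.75 ± 0.441 and did not pass the test (adjusted p = 0.641). Under quantile normalization its log2 change was -0.73 with an adjusted p of 0.0212, where its alternatives ran from 0.0212 to 0.999. Itgav and Cd44, whose products were used to part the groups, are no finding between the sorted populations. Ptprc, whose product a triple-negative gate would exclude from both groups, was past the test in all 19 alternatives.

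**Figure D1:**
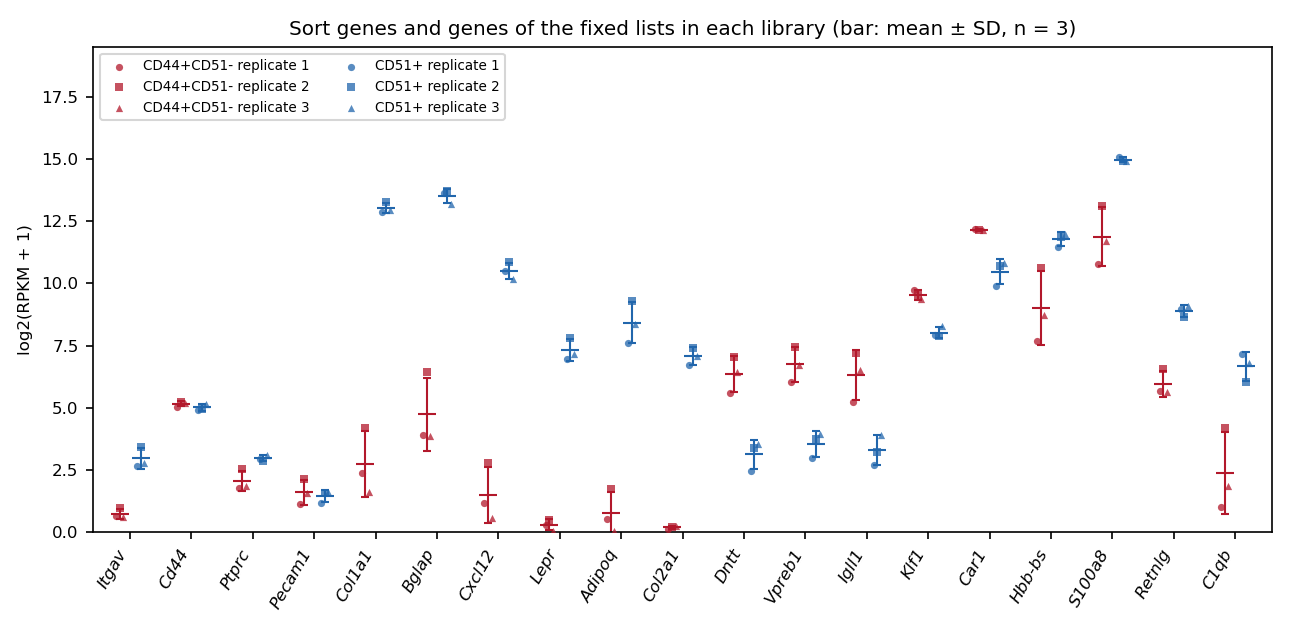
RPKM of 19 genes as log2(RPKM + 1), with a point per library and the mean ± SD of the 3 libraries of each sorted population. Itgav, Col1a1, Cxcl12, Lepr and Adipoq lie higher in all 3 CD51+ libraries, Dntt, Vpreb1, Klf1 and Car1 lie lower in all 3, and the points of Cd44 and Pecam1 overlap.

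CD51+ cells carried the transcripts of bone-forming and marrow stromal cells at far higher levels than CD44+CD51- cells, while early B cell genes and the red cell regulator genes Klf1 and Gata1 were higher in CD44+CD51- cells. Col1a1 (chromosome 11, 94936224 to 94953042, plus strand), the main collagen chain of bone, rose from 7.89 ± 8.30 to 8424 ± 1325. Cxcl12 (chromosome 6, 117168535 to 117181367, plus strand), the chemokine that holds stem and B cells in marrow, rose from 2.51 ± 2.88 to 1472 ± 343. Dntt (chromosome 19, 41029275 to 41059525, plus strand), the polymerase that adds bases at antigen receptor junctions, was at 87.2 ± 40.8 in CD44+CD51- cells and 8.19 ± 3.25 in CD51+ cells. Without CD44+CD51- replicate 2, the means of that group moved by more than 1.5 times for 48 of 123 named genes, to 3.14 for Col1a1 and 0.866 for Cxcl12 and, among genes given below, to 3.92 for Sparc, 13.8 for Bglap, 315 for Hbb-bs and 2542 for S100a8.

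Of 11741 genes tested, 2825 were higher and 3484 lower in CD51+ cells. Calls thus covered 53.7% of the genes, and 44.8% of the calls were higher. With the replicate block 3265 genes were higher and 4854 lower. The 3 values of each group did not overlap in 7466 genes, or 63.6%, where chance gives 10%. Rises were the larger changes: 1077 genes called higher and 14 called lower had means at least 10-fold apart. Beyond 2-fold, limma's treat called 1144 genes higher and 25 lower. The 25 became 82 with the replicate block and 9 under TMM, and 15, 13 or 8 without CD44+CD51- replicate 1, 2 or 3 and 14 or 6 without CD51+ replicate 1 or 2. The balance of directions depended on the scaling. Calls were 3286 higher and 2248 lower under TMM (59.4% higher), which moved the median log2 change of all genes by 0.20 from its value of -0.23, and 2419 higher and 4567 lower under quantile normalization (34.6% higher), which moved it by -0.13. Directions of small changes below are relative to these shifts.

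Libraries of the same group correlated across genes at r between 0.949 and 0.987 and libraries of different groups at r between 0.728 and 0.834. The first principal component held 84.6% of the variance and parted the groups. The second held 9.97% and parted the libraries numbered 1 of both groups from the other 4.

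**Figure D2:**
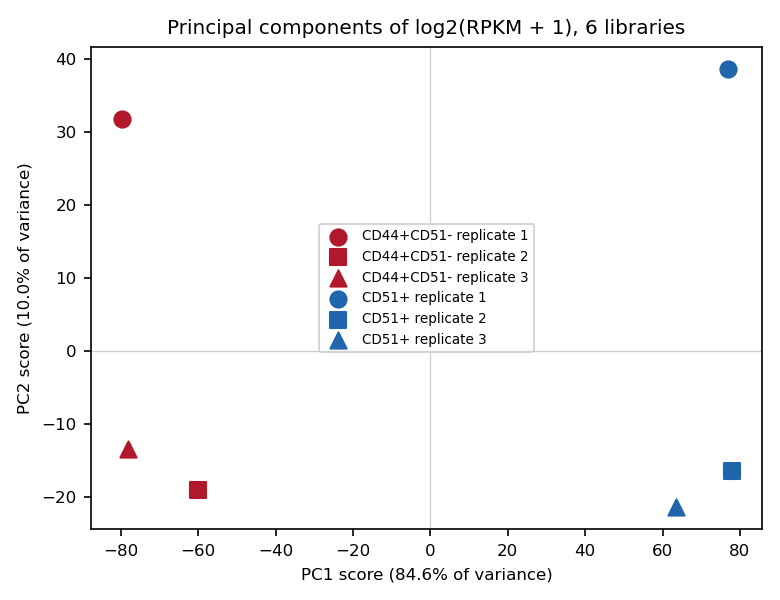
First and second principal components of log2(RPKM + 1) over 11741 genes, with a point per library, coloured by sorted population and marked with its number. The groups part along the first axis (84.6% of the variance), and along the second (9.97%) the libraries numbered 1 lie at 31.8 and 38.7 while the other 4 lie between -21.4 and -13.4.

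The 10 largest rises by the rule were Col1a1 (log2 change 10.30 ± 0.61 SE), Sparc, Col1a2, Dcn, Bglap2, Spp1, Ibsp, Cxcl12, Bglap and Lum (8.79 ± 0.37 SE). Sparc, a matrix protein that binds collagen, went from 15.5 ± 20.02 to 10515 ± 2213 RPKM, and Bglap, which encodes the bone hormone osteocalcin, from 37.4 ± 40.9 to 11889 ± 2194. Bglap and Bglap2 are close paralogs, so the split of reads between them is uncertain. The 10 largest falls were Dntt (-3.22 ± 0.42 SE), Vpreb1, Igll1, Vpreb2, Vpreb3, Cd79a, Prss50, Tfr2, Chchd10 and Egfl7 (-1.77 ± 0.47 SE). Of these, 6 are early B cell genes, and Tfr2 is a transferrin receptor of erythroid and liver cells, at 105 ± 12.8 and 28.6 ± 1.02. The call of Egfl7 was lost without CD51+ replicate 2 (adjusted p = 0.0630) or 3 (0.0597), in a range of 0.000111 to 0.0630 over its alternatives.

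Mesenchymal stromal markers were higher in CD51+ cells for 14 of 15 tested genes and lower for 1, with the same counts when adjusted over the list alone. Lepr (chromosome 4, 101717404 to 101815352, plus strand), the leptin receptor that marks perivascular stromal cells of marrow, rose from 0.230 ± 0.186 to 164 ± 53.5 (log2 change 7.03, adjusted p = 4.9e-06). Gas6, a ligand of TAM receptors, rose by a log2 change of 7.66, and Pdgfrb, a growth factor receptor of stromal and mural cells, by 5.74. Eng, the endoglin gene, was the member that fell, from 38.4 ± 12.3 to 15.8 ± 2.86. Niche factors, which act on blood cells from their surroundings, were higher for 15 of 16, and adjusted over the list alone for 15 with 1 lower. With the replicate block 1 was lower as well. Besides Cxcl12, Spp1, which encodes osteopontin, went from 3.05 ± 1.99 to 2290 ± 416, and the chemokine gene Cxcl14 from 0.775 ± 0.459 to 252 ± 69.3. Camera with the preset correlation gave adjusted p = 2.6e-09 for the stromal markers and 4.5e-09 for the niche factors, and adjusted p = 0.266 for each with an estimated correlation.

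Genes of 3 skeletal and fat lineages rose together. All 18 osteolineage genes tested were higher, also when adjusted over the list alone, with a median log2 change of 6.41. Ibsp, which encodes bone sialoprotein, rose from 3.09 ± 1.99 to 2205 ± 375. Of 10 adipogenic genes tested, out of 16 in the list, 9 were higher, and 10 when adjusted over the list alone. Adipoq (chromosome 16, 23146536 to 23158028, plus strand), the adiponectin gene, went from 0.918 ± 1.21 to 383 ± 218 and Lpl, lipoprotein lipase, from 0.583 ± 0.633 to 80.9 ± 19.1. Of 9 chondrogenic genes tested, out of 18 in the list, 8 were higher, by either adjustment. Col2a1 (chromosome 15, 97975602 to 98004695, minus strand), the main collagen of cartilage, rose from 0.138 ± 0.0459 to 137 ± 32.5. All 40 extracellular matrix genes tested were higher, also when adjusted over the list alone. The preset camera adjusted p was 7.1e-14 for the osteolineage, 6.5e-06 for the adipogenic, 1.2e-05 for the chondrogenic and 3.7e-22 for the matrix list. In the same order the adjusted p was 0.266, 0.287, 0.306 and 0.266 with an estimated correlation. No call that camera made with the preset correlation on any list held with an estimated correlation. The integrin list lost its call although its estimated correlation was -0.044, below the preset 0.01. A lost call therefore does not show by itself that correlation among the genes of a list accounts for it. The correlation is estimated from the spread within 3 libraries per group, so this form has little power. Even the matrix list, with all 40 genes higher, came to 0.266. A lost call in it weighs neither for nor against a list. Fry, which does not compare a list with other genes, gave an adjusted p between 0.000145 and 0.000608 for the osteolineage, adipogenic, chondrogenic, matrix and 2 stromal lists. Of lists below that camera called with the preset correlation, fry did not call ribosomal proteins (adjusted p = 0.0706), pan-haematopoietic (0.0813), mitosis (0.116) or mast, basophil and eosinophil genes (0.150). It called housekeeping (0.00898) and Schwann and neural genes (0.00500), which camera did not.

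In the BMP and TGF-beta pathway 26 of 29 genes were higher, and 27 when adjusted over the list alone. Fstl1, a secreted binding protein, rose from 0.175 ± 0.241 to 87.5 ± 21.1 and the ligand gene Bmp6 from 0.160 ± 0.129 to 66.2 ± 18.4. In the Wnt pathway 15 of 19 were higher and 2 lower by either adjustment, among them the secreted inhibitors Wif1 (log2 change 6.98) and Sfrp4 (6.21), while the receptor gene Fzd7 fell by 0.76 and Fzd6, named after its value was seen, by 0.60. Complement genes were higher for 10 of 11 and lower for 1 by either adjustment. Serping1, which encodes the C1 inhibitor, went from 1.90 ± 2.36 to 1020 ± 264 and C4b, a complement component, from 0.125 ± 0.0957 to 72.9 ± 29.6. The member that fell, Cd55, lost its call without CD44+CD51- replicate 2 (adjusted p = 0.0544) or 3 (0.0832) or CD51+ replicate 2 (0.0624), in a range of 0.00159 to 0.0832 over its alternatives. Chemokines and cytokines were higher for 10 of 12 by either adjustment, with Cx3cl1 rising by 4.53 and Ccl2 by 2.94. The preset camera adjusted p was 5.2e-13 for BMP and TGF-beta, 1.9e-06 for Wnt, 5.1e-06 for complement and 1.8e-05 for chemokines. With an estimated correlation the adjusted p was 0.306 for Wnt and 0.266 for the other 3 lists.

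Integrins other than Itgav were higher for 9 of 15 and lower for 2 by either adjustment. Itgb5, which pairs with αV, rose from 2.81 ± 0.778 to 33.6 ± 5.59, and Itga4, a subunit of the VCAM1 receptor on blood cells, was at 10.2 ± 2.48 and 4.37 ± 1.35 (adjusted p = 0.0125). The other fall, of Itga5, was named after its value was seen (adjusted p = 0.0470), and 1 integrin was lower without CD44+CD51- replicate 1 or 3 or CD51+ replicate 2. All 11 mural and smooth muscle genes were higher by either adjustment, with the Notch target gene Heyl at 1.83 ± 0.511 and 16.5 ± 10.2. Camera gave adjusted p = 0.0042 for integrins and 7.7e-06 for mural genes, and adjusted p = 0.266 and 0.306 with an estimated correlation. In the Schwann and neural list 2 of 4 were higher and 1 lower by either adjustment (camera adjusted p = 0.427). S100b was at 0 in all CD44+CD51- libraries and at 20.3 ± 9.43 in CD51+ cells, at least 194-fold higher against a floor of 3 reads per library. Ncam1 rose from 1.07 ± 0.826 to 10.2 ± 2.11, and Mbp, a myelin gene that blood cells also transcribe, fell by 1.07 on the log2 scale.

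**Figure D3:**
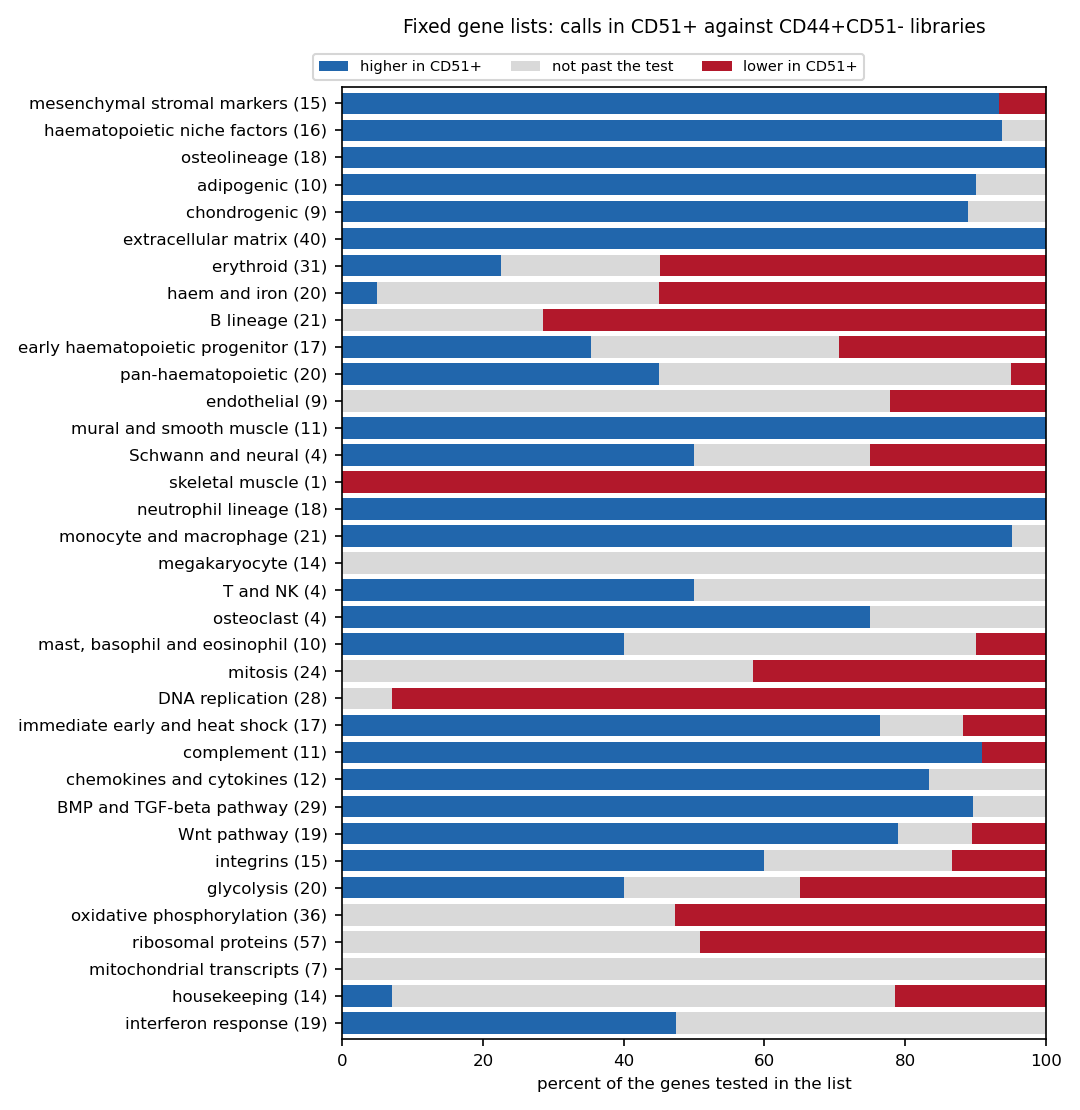
Percent of the tested genes of each list that were higher in CD51+ cells (blue), not past the test (grey) or lower (red) at an adjusted p under 0.05 by limma over all 11741 genes. The osteolineage, extracellular matrix, mural and neutrophil lists are wholly blue, the DNA replication list is red for 26 of 28 genes, and the erythroid list holds both colours.

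Genes of early B cells fell. Of 21 tested, 15 were lower in CD51+ cells and none higher, and 16 were lower when adjusted over the list alone. With the replicate block 2 members were called higher. Vpreb1 (chromosome 16, 16868403 to 16870843, minus strand) and Igll1, which encode the surrogate light chain of pre-B cells, were at 115 ± 55.6 and 91.7 ± 55.4 in CD44+CD51- cells and at 11.2 ± 3.89 and 9.36 ± 4.36 in CD51+ cells. Vpreb1 and Vpreb2 are close paralogs, so the split of reads between them is uncertain. Cd79a, a chain of the B cell receptor, fell by 1.96 on the log2 scale (adjusted p = 0.0111). The preset camera adjusted p was 0.000951 for the list, and adjusted p = 0.581 with an estimated correlation.

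Erythroid genes moved both ways. Of 31 tested, 17 were lower and 7 higher in CD51+ cells by either adjustment, and camera did not call the list (adjusted p = 0.124; median log2 change -0.97, mean -0.19). Klf1 (chromosome 8, 84901928 to 84905291, plus strand), a master regulator of globin and red cell genes, was at 750.2 ± 103 and 260.1 ± 41.1, and Gata1, its partner in erythroid commitment, at 228 ± 31.9 and 75.7 ± 7.10. Car1, the carbonic anhydrase of red cell precursors, was at 4574 ± 124 and 1473 ± 452. The 7 that rose were the globin genes Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2 with Alas2, Bpgm and Cd59a, of which all but Hbb-bs and Alas2 were chosen after their values were seen. Hbb-bs went from 735 ± 736 to 3551 ± 634 (log2 change 2.76, adjusted p = 0.0139). Without CD44+CD51- replicate 3, or without CD51+ replicate 3, the count of rises was 3. The globin pairs are close paralogs with uncertain read assignment. Alas2, the first enzyme of erythroid haem synthesis, rose from 29.1 ± 27.0 to 108 ± 19.9, and its call was lost without CD44+CD51- replicate 3 (adjusted p = 0.0502) or CD51+ replicate 3 (0.0511), in a range of 0.000216 to 0.0519 over its alternatives. Haem and iron genes were lower for 11 of 20 and higher for 1, and adjusted over the list alone for 12 and 1. With the replicate block 16 were lower and 2 higher. Steap3, the ferric reductase of erythroid endosomes, fell by 1.44 on the log2 scale and Cpox, an enzyme of haem synthesis, by 1.15. Camera gave adjusted p = 0.0111 for this list, and adjusted p = 0.486 with an estimated correlation. Globin transcripts made up 0.510 ± 0.430% of the summed RPKM in CD44+CD51- libraries and 1.62 ± 0.267% in CD51+ libraries (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). Without CD44+CD51- replicate 2 the mean of its group was 0.272%.

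Early progenitor genes were higher for 6 of 17 and lower for 5, and adjusted over the list alone for 7 and 5 (camera adjusted p = 0.369). Spi1, a myeloid regulator, rose from 20.01 ± 10.5 to 92.5 ± 38.4 and Cebpa, a regulator of granulocytes and fat cells that the adipogenic list also holds, from 1.87 ± 0.960 to 30.9 ± 10.05, while Gfi1b, a repressor of red cell and platelet precursors, was at 294 ± 21.6 and 97.4 ± 12.3. The others that fell were Kit, Myb, Gata2 and Lmo2, of which all but Gata2 were named after their values were seen. The 5 became 3 without CD44+CD51- replicate 2 or 3. Genes shared by white blood cells were higher for 9 of 20 and lower for 1 by either adjustment, with Cd52 at 41.9 ± 29.8 and 223 ± 33.9 and the actin-bundling gene Lcp1 at 18.03 ± 11.4 and 72.0 ± 5.51. With the replicate block 12 were higher and 3 lower, and 3 or 2 were lower without CD44+CD51- replicate 1 or CD51+ replicate 3. The member that fell, Ikzf1, lost its call without CD44+CD51- replicate 2 (adjusted p = 0.0954) or 3 (0.0960) or CD51+ replicate 2 (0.0549), in a range of 0.00266 to 0.0960 over its alternatives. Camera gave this list adjusted p = 0.0203, and adjusted p = 0.618 with an estimated correlation. Of 9 endothelial genes tested, Eng and Egfl7 were lower and none was higher by either adjustment (camera adjusted p = 0.817), with 2 higher and 4 lower under the replicate block. Without CD44+CD51- replicate 2 the list had 3 higher and 2 lower, and its median log2 change went from -0.16 to 0.10. Skeletal muscle had a single tested gene, Mylpf, lower with an adjusted p of 0.0325. It was not called without CD44+CD51- replicate 2 (adjusted p = 0.0943) or 3 (0.0904) or CD51+ replicate 1 (0.0666) or 2 (0.0790), in a range of 0.00116 to 0.0943 over its alternatives, and the set test gave 0.452.

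Myeloid genes were higher in CD51+ cells. All 18 genes of the neutrophil lineage list were higher by either adjustment, with a median log2 change of 2.57, or 14 of 18 under quantile normalization, and 20 of 21 monocyte and macrophage genes were higher by either adjustment, with a median of 2.56. S100a8 (chromosome 3, 90668978 to 90670035, plus strand), a calcium-binding protein of neutrophils, went from 4674 ± 3773 to 32112 ± 2072 RPKM (log2 change 3.10, adjusted p = 0.00765). Its adjusted p was 0.0832 under quantile normalization and 0.0824 with no filter, in a range of 0.00162 to 0.0832 over its alternatives. Retnlg, a neutrophil transcript, rose from 63.6 ± 25.4 to 481 ± 75.3 (adjusted p = 0.000250) and C1qb, which macrophages make, by a log2 change of 4.31 to 106 ± 39.5 (adjusted p = 0.00353). The neutrophil genes made up 3.19 ± 2.40% of the summed RPKM in CD44+CD51- libraries and 15.1 ± 0.461% in CD51+ libraries, and the 10 highest genes of each library 11.3 ± 1.26% and 26.8 ± 1.92% (exact permutation p = 0.1 for each, two-sided). The CD44+CD51- libraries held 1.29, 5.89 and 2.38% in neutrophil genes, and their mean without replicate 2 was 1.83%. Camera gave adjusted p = 1.9e-06 for the neutrophil and 3.9e-07 for the macrophage list, and adjusted p = 0.484 and 0.446 with an estimated correlation.

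Other blood lists were smaller. Osteoclast genes were higher for 3 of 4 by either adjustment, with the protease gene Ctsk at 0.251 ± 0.320 and 93.8 ± 23.0 and Mmp9 at 18.8 ± 9.62 and 112 ± 37.0 (camera adjusted p = 0.0328, and adjusted p = 0.446 with an estimated correlation). Nfatc1, the other member called higher, was past the test in only 8 of 19 alternatives, with an adjusted p between 0.0122 and 0.155 (0.0834 and 0.155 without CD44+CD51- replicates 1 and 3, and 0.101, 0.0859 and 0.112 without CD51+ replicates 1, 2 and 3). Mast, basophil and eosinophil genes were higher for 4 of 10 and lower for 1 by either adjustment, and higher for 7 with the replicate block. The 4 were Prss34, Mcpt8, Ear2 and Ccr3, the last named after its value was seen. Ear2, of a family of close paralogs, lost its call without CD44+CD51- replicate 3 (adjusted p = 0.0601) or CD51+ replicate 3 (0.0597), in a range of 0.00260 to 0.0601. Prss34, a basophil protease, was at 3.38 ± 4.72 and 112 ± 91.3 (61.0 without CD51+ replicate 3), and the progenitor and mast cell regulator Gata2 at 11.1 ± 2.78 and 4.54 ± 0.761. The list had camera adjusted p = 0.0448, and adjusted p = 0.618 with an estimated correlation. In the T and NK list 2 of 4 were higher by either adjustment, Nkg7 at 54.3 ± 41.5 and 180.3 ± 20.7 and Cd4 at 0.283 ± 0.259 and 2.35 ± 0.428 (camera adjusted p = 0.355), and 1 was lower under quantile normalization or without CD51+ replicate 3. No gene of the 14 in the megakaryocyte list passed limma's test by either adjustment (camera adjusted p = 0.817), 0 had an unadjusted p under 0.05, and limma's voom on recovered reads called 0. With the replicate block 1 was lower, and 1 and 4 were lower without CD44+CD51- replicate 2 and without CD51+ replicate 3. Pf4, a platelet chemokine, was at 179 ± 151 and 362 ± 508, and at 92.3 and 68.4 without the libraries numbered 3, so its direction rested on them.

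**Figure D4:**
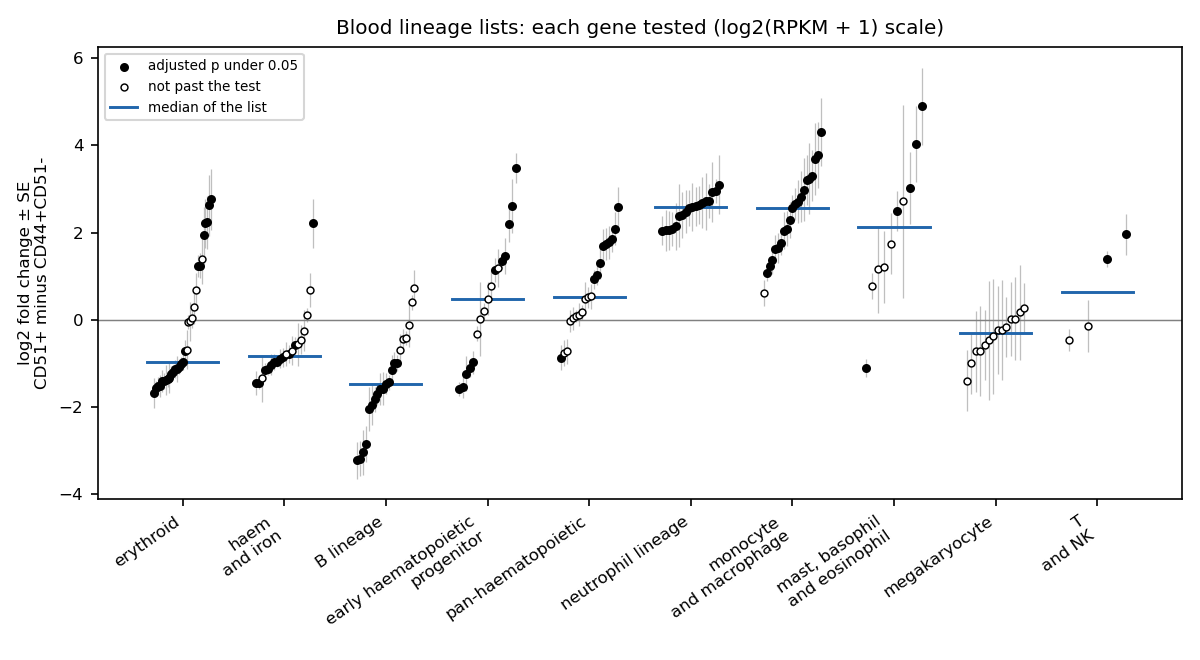
Log2 change ± SE (CD51+ minus CD44+CD51-, log2(RPKM + 1), n = 3 per group) of each tested gene in 10 lists of blood cell genes, filled where the adjusted p was under 0.05, with a blue line at the median of each list. All 18 neutrophil genes lie above 0, the 15 called B lineage genes lie below 0, and erythroid genes lie on both sides.

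Genes of DNA replication, and part of those of mitosis, ribosomes and respiration, were lower in CD51+ cells. DNA replication genes were lower for 26 of 28, and for 27 when adjusted over the list alone. Mcm10, which helps to start replication, fell by 1.22 on the log2 scale, and Mcm2, a subunit of the replicative helicase, was at 145 ± 12.4 and 63.3 ± 4.62. Mitosis genes were lower for 10 of 24, and for 7 when adjusted over the list alone. The 10 became 4 under TMM, and 4 or 5 without CD44+CD51- replicate 2 or 3 and 3 without CD51+ replicate 2. Ribosomal proteins were lower for 28 of 57, and for 22 when adjusted over the list alone, with Rpl5 at 121 ± 5.76 and 59.2 ± 11.9. That count was 56 with the replicate block, 10 under TMM, 5 without CD44+CD51- replicate 2 and 5 without replicate 3, and 16 or 8 without CD51+ replicate 1 or 2. Nuclear genes of oxidative phosphorylation were lower for 19 of 36 by either adjustment, with Uqcrc1, a subunit of complex III, at 308 ± 15.8 and 163 ± 7.53. The 19 became 10 under TMM, 11 or 10 without CD44+CD51- replicate 2 or 3 and 11 without CD51+ replicate 2. The preset camera adjusted p was 1.4e-06 for replication, 0.0308 for mitosis, 4.8e-05 for ribosomal proteins and 0.00103 for oxidative phosphorylation. In the same order the adjusted p was 0.446, 0.703, 0.618 and 0.618 with an estimated correlation.

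Glycolysis genes split, with 8 of 20 higher and 7 lower by either adjustment (camera adjusted p = 0.440). Under TMM 9 were higher and 2 lower, and with no filter 9 higher and 4 lower. The 7 became 4 without CD44+CD51- replicate 3 or CD51+ replicate 3, and 2 without CD51+ replicate 2. Of the pyruvate kinase genes, Pkm, the form of most tissues, went from 92.7 ± 46.9 to 375 ± 65.3, and Pklr, the form of red cells and liver, was at 52.0 ± 3.02 and 15.6 ± 1.27 (adjusted p = 9.0e-05). Ldhb, a lactate dehydrogenase subunit, rose from 4.93 ± 2.05 to 33.0 ± 2.91. Immediate early and heat shock genes, which tissue dissociation can raise, were higher for 13 of 17 and lower for 2, and adjusted over the list alone for 14 and 2. Fos went from 18.9 ± 12.3 to 115 ± 18.6 and Socs3 from 0.5002 ± 0.123 to 32.3 ± 27.3 (16.8 without CD51+ replicate 1), while the heat shock gene Hsph1 fell by 1.24 on the log2 scale. Dnajb1, named after its value was seen, fell by 0.64, and 1 gene was lower in place of 2 without CD44+CD51- replicate 2 or 3 or CD51+ replicate 2. Interferon response genes were higher for 9 of 19 by either adjustment, among them the transcription factor gene Irf1, at 4.19 ± 0.684 and 19.47 ± 2.44. Camera gave adjusted p = 0.000125 for the immediate early list and 0.000864 for the interferon list, and adjusted p = 0.306 for each with an estimated correlation.

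Of 14 housekeeping genes 1 was higher and 3 lower by either adjustment (camera adjusted p = 0.329), and 7 were lower with the replicate block. Sdha, of the respiratory chain, was at 212 ± 11.5 and 121 ± 2.97, and Tfrc, the transferrin receptor, at 99.0 ± 8.40 and 50.6 ± 9.71. Tbp, the other gene that fell, lost its call without CD44+CD51- replicate 2 (adjusted p = 0.0676) or 3 (0.0567) or CD51+ replicate 2 (0.0505), in a range of 0.00197 to 0.0676. B2m, the gene that rose, lost it without CD44+CD51- replicate 1 (0.0781) or 3 (0.0692), in a range of 0.00903 to 0.181. No gene of the 7 mitochondrial transcripts passed limma's test by either adjustment (camera adjusted p = 0.717), 0 had an unadjusted p under 0.05, and limma's voom on recovered reads called 0. Under quantile normalization 3 of the 7 were lower, among them mt-Cytb (log2 change -1.46). Under the replicate block mt-Nd1 (3193 ± 788 and 1895 ± 718) was lower with an adjusted p of 0.0226, in a range of 0.00806 to 0.302 over its alternatives. Mitochondrial genes held 3.30 ± 0.721% and 2.26 ± 0.804% of the summed RPKM in CD44+CD51- and CD51+ libraries (exact permutation p = 0.3, two-sided), and ribosomal RNA genes 5.73 ± 0.556% and 8.18 ± 0.439% (exact permutation p = 0.1, two-sided). The permutation did not use the library numbers. At numbers 1, 2 and 3 the mitochondrial share was 2.47, 3.70 and 3.74% in CD44+CD51- libraries. In CD51+ libraries it was 1.34, 2.65 and 2.80%, lower at each number.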

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

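The alternatives with voom on recovered reads, with the block and a GC correction, without both libraries numbered 1 and with rescaling outside ribosomal RNA and neutrophil genes were chosen after seeing the data. Counts of genes higher in CD51+ cells ran from 1613 (RPKM of at least 5) to 4006 (no filter), and counts of genes lower from 2248 (TMM) to 4854 (replicate block). Beyond 2-fold, 759 genes were higher at RPKM of at least 5, with fewer genes tested. The 25 genes lower beyond 2-fold became 57 with a pseudocount of 0.1, 13 with no filter, 9 under TMM, 78 under quantile normalization, 82 with the replicate block, 53 by voom and 48 with the block and a GC correction, and between 6 and 24 with each library left out in turn, where the cause was not tested. Of 123 named genes 116 passed the test and 100 passed it in every alternative in which they were tested, and none changed direction with a call. Leaving out replicates 1, 2 and 3 moved the mean of their group by more than 1.5 times for 2, 48 and 4 named genes in CD44+CD51- cells and 2, 0 and 5 in CD51+ cells. The share of the 10 highest genes differed by 15.4 points, and by 16.2 without mitochondrial genes.

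With an estimated correlation in place of the preset one, the adjusted p of the set test was 0.266 for stromal markers, niche factors, osteolineage, matrix, complement, chemokines, BMP and TGF-beta, and integrins. It was 0.287 for adipogenic genes, and 0.306 for chondrogenic, mural, immediate early, Wnt and interferon genes. It was 0.446 for macrophage, osteoclast and DNA replication genes, 0.484 for neutrophil, 0.486 for haem and iron, and 0.581 for B lineage genes. It was 0.618 for pan-haematopoietic, mast, oxidative phosphorylation and ribosomal protein genes and 0.703 for mitosis genes. With 3 libraries per group this form has little power, so these values weigh neither for nor against a list.

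Counts of list members with RPKM of at least 5, where fewer genes were tested, were 4 chondrogenic, 2 mural, 13 macrophage, 1 T and NK, 3 chemokine and 8 Wnt genes higher. With no filter they were 4 T and NK genes higher, 0 skeletal muscle genes lower and 10 ribosomal proteins, 4 glycolysis, 0 pan-haematopoietic and 1 mural genes lower, and 1 endothelial and 0 housekeeping genes higher. Under TMM they were 0 skeletal muscle, 0 complement, 0 pan-haematopoietic, 1 integrin, 1 immediate early, 2 glycolysis, 4 mitosis, 10 oxidative phosphorylation and 10 ribosomal protein genes lower, and 2 mitosis and 1 B lineage genes higher. Under quantile normalization they were 3 mitochondrial, 4 Wnt, 2 Schwann and neural, 1 chondrogenic, 1 T and NK, 1 integrin, 1 immediate early and 0 pan-haematopoietic genes lower and 0 housekeeping genes higher. With the replicate block they were 4 endothelial, 56 ribosomal protein and 7 housekeeping genes lower and 7 mast, basophil and eosinophil genes higher. With the block and a GC correction they were 53 ribosomal protein, 6 housekeeping, 3 pan-haematopoietic, 1 megakaryocyte and 1 mitochondrial genes lower. In that setting 7 mast, basophil and eosinophil, 15 interferon, 2 mitosis, 1 megakaryocyte, 2 endothelial, 2 B lineage, 2 haem and iron and 2 housekeeping genes were higher. Without both libraries numbered 1 they were 53 ribosomal protein, 6 housekeeping, 3 pan-haematopoietic, 1 niche factor and 1 mitochondrial genes lower and 0 haem and iron genes higher. With rescaling outside ribosomal RNA and neutrophil genes they were 3 pan-haematopoietic and 1 niche factor genes lower. With each library left out in turn, members lower ran from 2 to 3 for endothelial, 0 to 1 for skeletal muscle, 3 to 11 for mitosis, 10 to 18 for oxidative phosphorylation and 5 to 28 for ribosomal protein genes. Without CD44+CD51- replicate 3 or CD51+ replicate 3 no haem and iron gene was higher, and without CD51+ replicate 1 a niche factor was lower. Without CD44+CD51- replicate 2 the endothelial list had 2 lower and 3 higher, and its median turned positive. The cause of these shifts was not tested, apart from the number of genes tested. Other than these counts, those given beside each list and mt-Nd1, the replicate block ended or turned no call among the main counts, the set tests and the named genes.

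Depth limits the genes of low abundance. It is known only through the library size that the RPKM had been divided by, estimated at 12197833 to 32517059 reads. Simulated sets with a fixed coefficient of variation of 20% recovered 65.6% of changes of 2-fold, so a small change that did not pass the test is not shown to be absent. Those sets changed only genes with enough expected reads, so the recovery of genes of low abundance was not measured.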

Other observations

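The gene families, the scaling test, both tests of a common background and the test of a share of CD44+CD51- cells were chosen only after the results were seen, whereas the tests of GC, length and other splits were set before. For 7 gene families, most tested members were higher in CD51+ cells. These families lie outside the fixed lists, apart from Hoxa7 and Hoxa9, which the early progenitor list also holds. All 4 insulin-like growth factor binding proteins tested were higher, with Igfbp5 at 0.0927 ± 0.0902 RPKM in CD44+CD51- cells and 134 ± 64.4 in CD51+ cells (n = 3 per group) and Igfbp7 at 4.08 ± 5.47 and 662 ± 210.3. Hox genes, which record position along the body, were higher for 7 of 8 (Hoxa10 log2 change 3.75), and under quantile normalization 1 was also lower. ADAMTS proteases, which trim the matrix, were higher for 7 of 8 and lower for 1 (Adamts2 log2 change 5.86). Semaphorins were higher for 8 of 10 and ephrins and Eph receptors for 6 of 7. All 4 connexins were higher, or 2 under quantile normalization, with Gja1 at 23.1 ± 1.89 and 584 ± 188.5. KDEL receptors and protein disulfide isomerases, which serve the export of proteins, were higher for 5 of 7 (Kdelr3 log2 change 6.40).

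For other families most calls were lower in CD51+ cells. All 7 CCT chaperonin subunits tested were lower, also under TMM and under quantile normalization. Of 18 tRNA synthetases 17 were lower, with 14 under TMM and 15 under quantile normalization, and Iars was at 62.9 ± 5.41 and 26.7 ± 0.517. Genes named Eif were lower for 38 of 55 and higher for 1, and 32 were lower under TMM. They are translation initiation factors together with kinases and binding proteins that act on such factors and some pseudogenes. Nop and Utp factors of ribosome assembly were lower for 12 of 15 (Nop2 log2 change -1.33). Proteasome subunits were lower for 25 of 38 and higher for 1, and 10 were lower under TMM. Histone genes, core and linker, were lower for 5 of 43, for 2 under TMM, for 20 under quantile normalization and for 22 with the replicate block, where 2 were higher.

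The count of 6309 genes differing between the groups was set against the other splits of the 6 samples, of which the highest gave 0 genes. Only 1 of the 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The other splits that also part 3 pairs of equal number gave 0 genes as well.

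Neutrophil, macrophage and globin genes were higher in CD51+ libraries, with S100a8 at 32112 ± 2072, C1qb at 106 ± 39.5 and Hbb-bs at 3551 ± 634 RPKM (n = 3), although a triple-negative gate would remove most neutrophils and red cells; no other list holds the neutrophil or macrophage genes. Over 3 other scalings of the RPKM values the lowest median log2 change of the 18 neutrophil genes was 2.30, so none of these 3 removed the rise. The limit for this test was set after the values were seen, and other scalings were not covered. S100a8 went from a log2 change of 3.10 to 1.68 under quantile normalization, where its adjusted p by limma was 0.0832. A first form of this test, the count of called genes, was dropped after it gave 14 of 18 under quantile normalization. A single background of constant makeup would keep the gap between 2 sets of genes the same in each library. For the median log2 level of macrophage minus neutrophil genes per library, the groups differed by 0.835 at a pseudocount of 0.1, where the CD44+CD51- libraries had an SD of 0.411, and by between -0.0347 and 1.18 over 4 pseudocounts. For globin minus neutrophil genes they differed by -0.109, with an SD of 0.571. A background that brings either pair together thus cannot be told apart from separate sources, since the gap between the groups was 0.285 for the first pair, less than that SD, and turned on the pseudocount, and the groups overlapped for the second. A first form of these tests and of the next permuted genes, and was dropped since genes of a list are not independent; a second set a bound on p that 3 against 3 cannot reach. Ptprc, which encodes CD45, was higher as well, at 3.25 ± 1.28 RPKM in CD44+CD51- libraries and 6.87 ± 0.643 in CD51+ libraries. RNA or cells of other marrow types in the sort, and myeloid cells that carry αV themselves, both stay open and untested.

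Erythroid genes remained abundant in CD51+ libraries, with Car1 at 1473 ± 452 RPKM. With the 4 globin genes, which rose, taken out of the erythroid list, erythroid genes kept a median of 46.8% of their CD44+CD51- level and B lineage genes 24.7% (27 and 16 genes with a mean RPKM of at least 5 in CD44+CD51- cells). For the median log2 level of these erythroid genes minus B lineage genes per library, the groups differed by 0.784 at a pseudocount of 0.1, with an SD of 0.587 in CD44+CD51- libraries, and by at least 0.629 over 4 pseudocounts. The groups overlapped at 3 of these, and at 0.5 the gap between them was 0.00552. A single share of CD44+CD51- cells among the CD51+ cells therefore cannot be told apart from other causes with 3 libraries per group. That erythroid and B lineage RNA may have entered in different shares, or that some erythroid cells carry CD51, was not tested.

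The libraries numbered 1 deviated together from their groups, with 112 genes above and 59 below their group mean by more than 0.8 on the log2 scale in both, where numbers 2 had 5 and 12 and numbers 3 had 23 and 15. Their deviations followed GC content across genes at r = 0.207 and 0.321. GC content bias is argued against as the whole cause, since the correlation of the pair stayed at 0.593 after each library's GC trend was removed, from 0.615 before. Length bias is argued against likewise, with 0.598 after removal of the length trend. A shared day, animal or library batch may lie behind the pattern and stays open, since the labels give none, and no biological explanation was tested.

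All 14 megakaryocyte genes tested were highest in the library numbered 3 of each group, by a median ratio of 3.71 to the mean of the other libraries in CD44+CD51- cells and 11.02 in CD51+ cells. CD44+CD51- replicate 2 was the highest of its group for 18 of 18 neutrophil, 21 of 21 macrophage and 17 of 18 osteolineage genes, at a median of 37.7%, 26.6% and 0.476% of the CD51+ mean. It was also the highest for 22 of 24 mitosis, 19 of 21 B lineage, 18 of 20 pan-haematopoietic and 7 of 7 mitochondrial genes. All called mitosis and B lineage genes were lower in CD51+ cells, so ranking highest was not particular to lists higher there. The size of the excess differed between lists. The median log2 excess of this library over replicates 1 and 3 was 1.76 for neutrophil, 2.49 for macrophage and 1.83 for osteolineage genes. It was 0.30 for mitosis, 0.97 for B lineage, 0.77 for pan-haematopoietic and 0.50 for mitochondrial genes. Among lists mostly called higher in CD51+ cells it was also small for chondrogenic (0.53), Wnt (0.24), integrin (0.24) and interferon genes (0.11). Its size thus did not follow the direction of a list alone. The cause was not tested.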
